A study of Homo sapiens with 6 samples.

How the data were processed

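Per the labels' protocols, THP-1 cells were differentiated with PMA, LPS and interferon gamma, treated for 48 h, and total RNA was extracted with a TAKARA kit. Libraries were made from 1 µg of RNA with the NEBNext Ultra RNA kit. Per the submitters' processing notes, reads were handled with HISAT2 on GRCh38, without versions. The quantification program, its annotation and the rule by which genes were kept are not given in the sources used here.

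The signal values are expression values that the authors normalized for gene length and sequencing depth before they were deposited, and whether they are FPKM or TPM is not stated. The 6 tables held the same 8842 genes, 7833 with an Ensembl ID and 1009 new genes without a name. Gene names came from the name table in the reference, which had 7818 of the IDs, and GENCODE release 29 on GRCh38, used for coordinates and exon overlaps, had 7819, of which 7814 are protein coding among 19951 such genes in that release. Of 681 symbols in the gene lists 464 were found.

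The design, most of the alternatives, the 33 gene lists and the naming rule were fixed before the data were examined. The design assumed read counts first and named a fallback for normalized values, which was the one used. Count-based tests and the planned minimum of 50 counts were not run because the tables hold no counts. The stricter filter, the fit without a trend, the subtraction of a control share, and the tests of carried-over control transcripts, of exon overlap and of osmotic genes were added later.

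Values were taken as log2(value + 1), which understates changes of weakly expressed genes. Genes with a value of at least 1 in at least 2 libraries were kept, 7648 in all, and 0 libraries were left out. All 3 groups entered one limma fit with an expression trend (prior degrees of freedom 3.89, residual degrees of freedom 3). Benjamini-Hochberg adjustment ran over all genes tested in a comparison, with a threshold of 0.05. No scaling was added to that of the authors. Values at 0 in the treated libraries were kept; the housekeeping ubiquitin gene UBB was among the genes at 0 in both oxLDL plus glucose libraries.

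Lists with at least 5 tested members, 30 of 33, were tested with camera at its preset correlation of 0.01. Beside it ran camera with an estimated correlation and fry, each with Benjamini-Hochberg adjustment over the lists of a comparison. The run with an estimated correlation rests on 3 residual degrees of freedom, which alone can keep lists from being called. The lists covered LXR targets, SREBP1 and SREBP2 targets, scavenger receptors, PPAR and lipid droplet genes, NRF2, ATF4 and endoplasmic reticulum stress, interferon, NF-kB, inflammasome, macrophage and other cell types, metabolism, cell cycle, p53, matrix, adhesion, metallothioneins, ribosomal proteins and histones.

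Named genes were, in each comparison, the 6 largest increases and the 6 largest decreases passing the test with a mean of at least 3 log2 units, a gene symbol and groups that do not overlap. To these were added the 3 genes of smallest p of each called list, up to 30 genes, and 12 genes chosen in advance. Where fewer than 12 genes passed, the 12 smallest p were taken instead. Some of the genes so picked are not reported here. Other genes were chosen after their values were seen.

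A self-test drew data with 200 changed genes among 7648, 20 times, for oxLDL plus glucose against oxLDL. With spreads taken from the moderated fit, 87.3%, 99.3% and 99.9% of genes changed by 1.5, 2 and 4 fold were recovered and 6.24% of called genes were unchanged. A second version with spreads drawn from the fitted prior, added after the first result was seen, recovered 66%, 94.3% and 99.8% with 4.86% unchanged. In both, camera called 100% of lists shifted by 0.5 log2 units and 0% of unshifted lists, at an unadjusted p under 0.05. Changed genes were taken from those with an oxLDL mean of at least 3 log2 units, and fewer changed genes were not tried. Genes were drawn independently, whereas the interferon lists had estimated correlations of 0.55 and 0.57. The self-test therefore does not cover correlated lists or smaller shifts.

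Alternatives were quantile normalization, column totals, no filter or a stricter filter, a pseudocount of 0.1, no expression trend, a replicate term, only the 4 libraries compared, a minimum log2 fold change of 1, each library left out in turn, and subtraction of a control share from oxLDL replicate 2. The tools were Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.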

Results

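RNA was sequenced from THP-1 cells, a human monocytic leukemia line, that had been differentiated into macrophages with the phorbol ester PMA, bacterial lipopolysaccharide (LPS) and interferon gamma. The cells then spent 48 h without further treatment (control), with oxidized low-density lipoprotein (oxLDL, the modified lipoprotein that macrophages take up as they turn into foam cells) or with oxLDL and glucose. Each of the 3 groups had 2 libraries, which the series text calls biological replicates. That text sets high glucose medium against medium without glucose for the oxLDL cultures, while the doses and the glucose level of the control were not given in the sources used here.

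Each library held a value for the same 8842 genes, normalized by the authors for gene length and sequencing depth. The values of a library summed to between 226962 and 231455, and the read depth behind them is unknown, so no counting error can be attached to a value. Log2 values correlated across genes with r = 0.9933 between the control libraries, 0.9915 between the oxLDL libraries and 0.9931 between the oxLDL plus glucose libraries. Treated libraries correlated with controls at r between 0.7005 and 0.7311, and oxLDL libraries with oxLDL plus glucose libraries at r between 0.9882 and 0.9916. Genes are not independent replicates, and these correlations describe the libraries only.

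The genes listed held almost none that were alike between control and treated cells. Of 7648 genes tested, 84 (1.1%) lay within 0.2 log2 units of equality between oxLDL and control and 79 (1.03%) between oxLDL plus glucose and control, against 5888 (76.99%) between the oxLDL groups. Shares of changed genes against control, and tests that set a gene list against the other genes, therefore had almost no unchanged genes to stand against.

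What oxLDL treatment changed in these macrophages was addressed by oxLDL against control. No measure of lipid uptake was among the values used here, so lipid loading of the cells was not shown. The glucose level of the control medium is not given, nor whether control and treated libraries came from the same starting culture. Rises and falls with oxLDL are therefore differences from control, in which oxLDL, medium and culture cannot be told apart. OLR1, which encodes the oxLDL receptor LOX-1, rose from 7.6 ± 0.28 to 154 ± 2.8 (SD, n = 2; log2 fold change 4.17, SE 0.06, limma with Benjamini-Hochberg adjusted p = 1.7e-07). CD36, a receptor for oxidized lipoproteins, rose from 22.3 ± 1.7 to 92.2 ± 4.5 (log2 fold change 2.00, SE 0.12, limma adjusted p = 4.3e-06). MSR1, the class A scavenger receptor, went the other way, from 204 ± 1.8 to 0.208 and 2.67 in oxLDL replicates 1 and 2 (log2 fold change −6.61, SE 0.44, limma adjusted p = 8.2e-06). The cholesterol exporters ABCG1 and ABCA1 also fell, ABCG1 from 13.8 ± 0.46 to 0.177 ± 0.18 and ABCA1 from 48.1 ± 1.8 to 27 ± 0.35, with log2 fold changes of −3.66 and −0.81. PLIN2, which coats lipid droplets, fell from 136 ± 4.8 to 65.4 ± 2.4.

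Other genes of lipid and sugar handling that had been chosen in advance were split in the same way. HMOX1, which degrades heme under oxidative stress, rose from 59 ± 4.4 to 153 ± 2.1. TXNIP, a glucose-induced inhibitor of glucose uptake, fell from 512 ± 6.4 to 201 ± 14, and SLC2A1, the glucose transporter GLUT1, from 81.8 ± 2.9 to 6.88 ± 0.81. The log2 fold changes of these genes were 1.36, −1.35 and −3.40 (limma adjusted p between 4.6e-07 and 3.6e-06). HMGCS1 and IL1B had been chosen as well and were not analysed here. In GRCh38 coordinates from GENCODE release 29, OLR1 (ENSG00000173391) lies on chromosome 12 at 10158301 to 10172138 and CD36 (ENSG00000135218) on chromosome 7 at 80369575 to 80679277. MSR1 (ENSG00000038945) lies on chromosome 8 at 16107878 to 16567490 and ABCG1 (ENSG00000160179) on chromosome 21 at 42199689 to 42297244. All of these genes are protein coding, and each value covers the whole gene rather than a single exon or untranslated region.

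**Figure D1:**
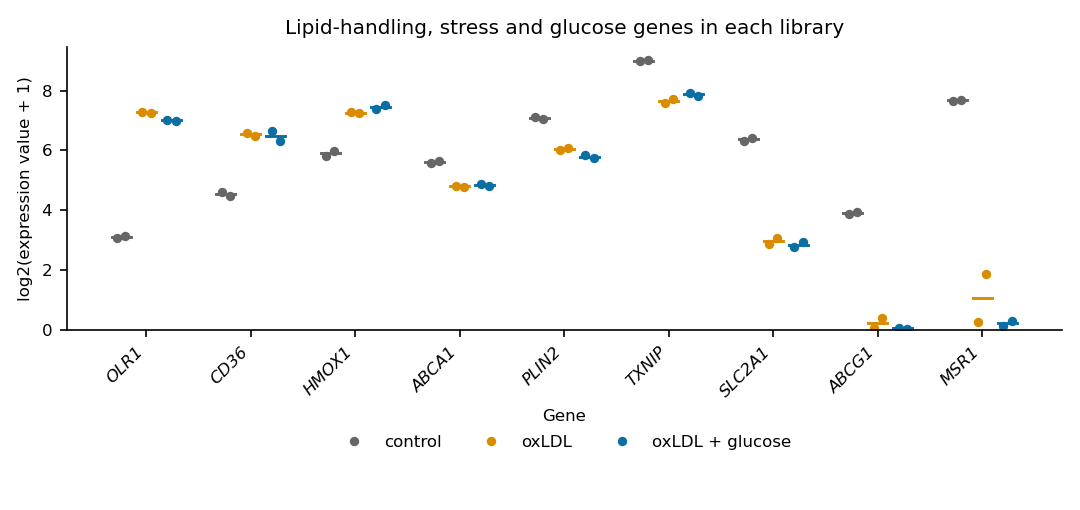
Expression of lipid and glucose genes chosen in advance, as log2(value + 1) on the vertical axis, with dots for the 2 libraries of each group and a line at the mean. OLR1 rises from 7.6 in control to 154 with oxLDL and 128 with oxLDL plus glucose, while MSR1 falls from 204 to 0.208 and 2.67 in the oxLDL libraries and 0.0934 and 0.224 with oxLDL plus glucose.

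Preset lists around these genes held members moving both ways. Of 13 genes of the scavenger receptor list, 5 rose and 8 fell, of 10 LXR targets and efflux genes 4 rose and 6 fell, and of 17 SREBP2 targets of cholesterol synthesis and uptake 10 rose and 7 fell. Fatty acid synthesis genes (SREBP1 targets) split 4 to 4 and genes of PPAR and the lipid droplet split 5 to 9, with HILPDA not passing. None of these 5 lists was called by camera, with adjusted p between 0.44 and 0.83. For all 33 lists in both comparisons with control, counts adjusted over the list alone were equal to the counts over all genes tested.

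Every tested member of both interferon lists and of the NF-kB list fell with oxLDL. All 30 type I interferon genes tested fell, with a median log2 fold change of −4.25 (camera adjusted p = 3.1e-09; adjusted p = 0.41 with an estimated correlation). OAS1 and IFIH1, sensors of viral RNA, fell from 89.6 ± 1.8 to 7.98 ± 0.75 and from 75.6 ± 0.82 to 6.58 ± 0.52, and IFI27 from 111 ± 4.6 to 0.731 ± 0.3. All 30 interferon gamma and antigen presentation genes fell as well, with a median of −3.37 (camera adjusted p = 2.5e-08; adjusted p = 0.44 with an estimated correlation). Among them the immunoproteasome subunit PSMB9 fell from 228 ± 0.88 to 36.5 ± 3.2 and the tryptophan tRNA ligase WARS1 from 2210 ± 1.6 to 247 ± 21. All 20 genes of the NF-kB list fell, with a median of −2.12 (camera adjusted p = 2e-06; adjusted p = 0.34 with an estimated correlation). They included the monocyte chemokine CCL2, from 142 ± 1.9 to 8.27 ± 0.35, the mitochondrial superoxide dismutase SOD2, from 1360 ± 170 to 88.9 ± 7.3, and the cytokine subunit EBI3, from 98 ± 2 to 19.5 ± 0.5.

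The most strongly lowered genes stood lower in oxLDL replicate 1 than in replicate 2. CTSL, the lysosomal protease cathepsin L, stood at 3460 and 3490 in the control libraries and at 3.4 and 54 in oxLDL replicates 1 and 2 (log2 fold change −7.80, SE 0.99, limma adjusted p = 0.00019). IDO1, which breaks down tryptophan, went from 1630 ± 15 to 1.71 and 25.4 and the chemokine CXCL10 from 507 ± 12 to 0.37 and 7.6. The small GTPase RND3 went from 334 ± 1.3 to 0.177 and 4.98 and the guanylate-binding proteins GBP1 and GBP5 from 653 ± 4.2 to 2.35 and 12 and from 1020 ± 24 to 3.74 and 21.1. Across 41 such transcripts, selected after the data were seen for a control mean of at least 20 and at most 0.2% of it in both oxLDL plus glucose libraries, the median share of the control level was 0.102% in oxLDL replicate 1 and 1.45% in oxLDL replicate 2. CTSL lies on chromosome 9 at 87725519 to 87731393 and IDO1 on chromosome 8 at 39902275 to 39928444.

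The lists of ribosomal proteins, cell cycle, oxidative phosphorylation and endoplasmic reticulum chaperones lay higher with oxLDL. All 40 ribosomal protein genes tested rose with oxLDL, with a median log2 fold change of 1.53 (camera adjusted p = 5.3e-10; adjusted p = 0.29 with an estimated correlation), among them RPL3 from 121 ± 2.3 to 628 ± 16 and RPS4X from 100 ± 2.5 to 512 ± 5.5. Of 27 cell cycle genes 26 rose and CCNE2 did not pass, with a median of 1.24 (camera adjusted p = 1.5e-05; adjusted p = 0.29 with an estimated correlation). The S phase regulator E2F1 rose from 0.209 ± 0.065 to 7.57 ± 0.041, the replication helicase subunit MCM3 from 6.09 ± 0.19 to 21.8 ± 1.2 and thymidine kinase TK1 from 0.332 ± 0.12 to 4.53 ± 0.11. Of 28 oxidative phosphorylation genes 26 rose and 1 fell, with a median of 1.00 (camera adjusted p = 3.4e-05; adjusted p = 0.29 with an estimated correlation). SDHA, NDUFS7 and COX4I1, subunits of respiratory complexes, rose with log2 fold changes of 2.41, 1.66 and 1.23. All 14 genes of the endoplasmic reticulum chaperone list rose, with a median of 1.01 (camera adjusted p = 0.00013; adjusted p = 0.29 with an estimated correlation).

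Among genes with a mean of at least 3 log2 units, the largest increases passing the test were in FLNA, which crosslinks actin, from 8.43 ± 0.24 to 336 ± 10, and PRG2, the eosinophil major basic protein, from 3.9 ± 0.53 to 162 ± 0.16. The lipid transfer protein TNFAIP8L3 rose from 6.68 ± 0.12 to 181 ± 0.023 and the NOTCH-pathway regulator DLK1 from 4.14 ± 0.095 to 120 ± 0.41. The tetraspanin CD9 rose from 4.68 ± 0.73 to 114 ± 1.9 and IGFN1 from 3.24 ± 0.33 to 81 ± 7.1. Log2 fold changes of these 6 genes ran from 4.27 for IGFN1 to 5.16 for FLNA, with limma adjusted p between 1.7e-07 and 3.5e-07. FLNA (ENSG00000196924) lies on chromosome X at 154348524 to 154374638.

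Among the remaining lists, histone genes fell in 7 of 7 (camera adjusted p = 0.0066; adjusted p = 0.34 with an estimated correlation) and genes of the metallothionein list, which holds 5 metallothioneins, their activator MTF1 and the zinc exporter SLC30A1, in 7 of 7 (camera adjusted p = 0.0066; adjusted p = 0.29 with an estimated correlation), although reads of histones and metallothioneins can be shared between near-identical copies. Of 13 inflammasome genes 11 fell and 2 rose (camera adjusted p = 0.014; adjusted p = 0.29 with an estimated correlation). The 5 markers of undifferentiated monocytic leukemia cells tested, granule genes such as AZU1 among them, all fell (camera adjusted p = 0.025; adjusted p = 0.33 with an estimated correlation). Lysosome genes fell in 15 of 19 (camera adjusted p = 0.043; adjusted p = 0.41 with an estimated correlation). Targets of p53 fell in 12 of 15 (camera adjusted p = 0.049; adjusted p = 0.52 with an estimated correlation), a call that ended without oxLDL replicate 1 (adjusted p = 0.056).

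Lists of cell types gave mixed pictures. Of 13 macrophage identity markers 10 fell and 3 rose (camera adjusted p = 0.075), of 4 monocyte markers 2 rose and 2 fell, and all 4 dendritic cell markers tested fell. Of 6 genes listed as non-myeloid markers 5 rose and 1 fell (camera adjusted p = 0.075). The largest increases were those of PECAM1, from 14 ± 0.45 to 96 ± 2.1, and VWF, from 0.0534 ± 0.00042 to 6.4 ± 0.049. PECAM1 was already expressed in the control macrophages, so its rise alone does not mark another cell type. VWF stood near 0 in control, and whether its rise marks another cell type was not tested. Genes of the NRF2 response (5 rose and 8 fell), the ATF4 response (5 and 9), alternative activation (3 and 8) and TREM2 macrophages (5 and 7) were not called. Those of glycolysis (6 and 8) and of glucose response and glucose side pathways (6 and 4) were not called either. Nor were those of hypoxia (3 and 5), NADPH oxidase (3 and 3), matrix (8 and 8) and leukocyte adhesion (3 and 7), and the 3 mitochondrially encoded transcripts tested all rose.

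In total 7347 of 7648 genes (96.1%) changed by limma at an adjusted p under 0.05, 3685 upward and 3662 downward, and 1809 and 1890 of them moved by at least 1 log2 unit. Camera called 13 lists with its preset correlation, 4 higher and 9 lower, and 0 with an estimated correlation. With 2 libraries a group, an exact two-sided permutation test of a single gene can give no p below 0.333, so these calls rest on the spread that limma shares across genes.

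**Figure D2:**
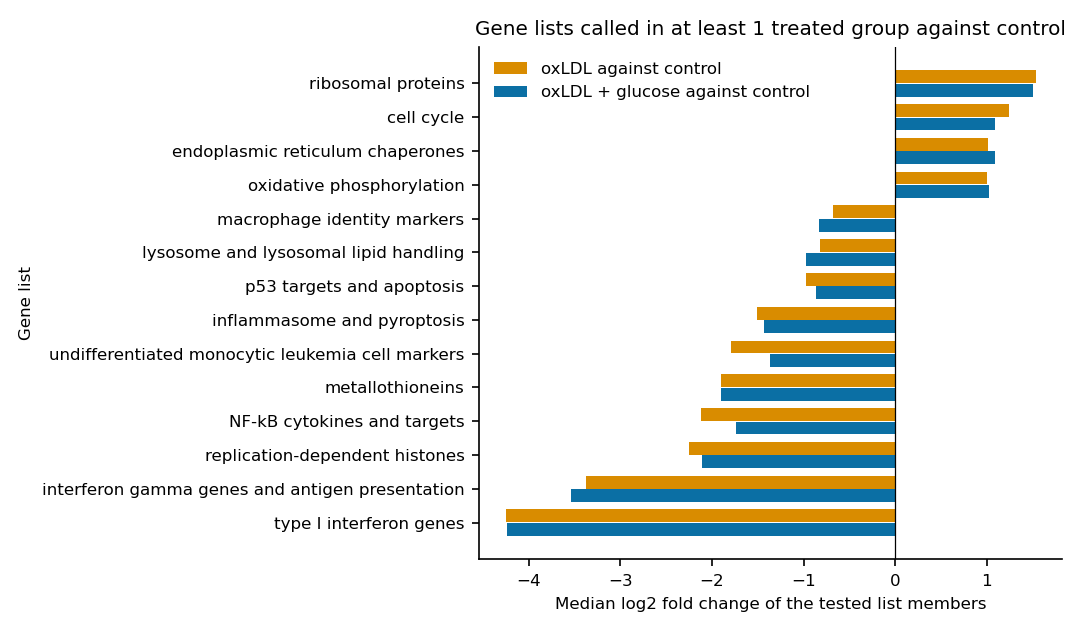
Median log2 fold change (horizontal axis) of the tested members of each gene list called in at least 1 treated group against control, with 1 bar for oxLDL and 1 for oxLDL plus glucose. Medians run from −4.25 for type I interferon genes to 1.53 for ribosomal protein genes with oxLDL, and the bars of the groups lie close together.

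Cells treated with oxLDL in the presence of glucose differed from the same controls in the same receptors. OLR1 rose from 7.6 ± 0.28 to 128 ± 1.4 (SD, n = 2; log2 fold change 3.91, SE 0.06, limma with Benjamini-Hochberg adjusted p = 1.4e-07) and CD36 from 22.3 ± 1.7 to 88.2 ± 15. MSR1 fell from 204 ± 1.8 to 0.158 ± 0.092, ABCG1 from 13.8 ± 0.46 to 0.0276 ± 0.0026, ABCA1 from 48.1 ± 1.8 to 27.9 ± 0.8 and PLIN2 from 136 ± 4.8 to 54.2 ± 2.7. HMOX1 stood at 175 ± 11, TXNIP at 234 ± 9.3 and SLC2A1 at 6.19 ± 0.56, with log2 fold changes against control of 1.55, −1.13 and −3.53 (limma adjusted p between 3.8e-07 and 5.4e-06).

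The largest increases were again in PRG2, to 250 ± 16, FLNA, to 314 ± 32, DLK1, to 131 ± 16, IGFN1, to 101 ± 0.99, TNFAIP8L3, to 181 ± 10, and CD9, to 128 ± 12, with log2 fold changes between 4.51 and 5.68. The largest decreases were in CTSL, listed at 0 and 0.181 in the libraries of this group, IDO1, at 0.305 and 0.523, CXCL10, at 0.32 and 0.203, RND3, at 0.174 and 0.172, GBP1, at 1.71 and 1.27, and HLA-DRB1, a class II antigen presentation gene whose reads can be shared with its paralogs, at 0.363 and 0.662. Their log2 fold changes on the log2(value + 1) scale lay between −7.91 and −11.64 (limma adjusted p between 8e-06 and 3.1e-05). IFI27 was listed at 0 in both libraries.

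All 13 lists called for oxLDL were called here in the same direction. Every tested gene of the type I interferon, interferon gamma and NF-kB lists fell, with medians of −4.24, −3.54 and −1.74 (camera adjusted p = 1.8e-09, 1.2e-08 and 4.2e-06; adjusted p = 0.40, 0.42 and 0.32 with an estimated correlation). OAS1 fell to 6.74 ± 0.076, IFIH1 to 6.03 ± 0.2 and PSMB9 to 38.1 ± 0.29. WARS1 fell to 209 ± 21, CCL2 to 13 ± 0.21, SOD2 to 80.8 ± 3.2 and EBI3 to 16.8 ± 0.48. Ribosomal protein genes rose in 40 of 40, cell cycle genes in 27 of 27, oxidative phosphorylation genes in 26 of 28 and genes of the endoplasmic reticulum chaperone list in 14 of 14, with medians of 1.5, 1.09, 1.02 and 1.09 (camera adjusted p between 6.9e-10 and 0.00014; adjusted p = 0.28 with an estimated correlation for each). RPL3 rose to 605 ± 13, RPS4X to 542 ± 43, E2F1 to 7.23 ± 0.36, MCM3 to 22.4 ± 1.1 and MCM7, another helicase subunit, to 19.6 ± 1.5. Respiratory subunits rose as well, SDHA to 153 ± 11, NDUFS7 to 40.1 ± 1.3 and COX4I1 to 250 ± 16.

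Histone genes and members of the metallothionein list fell in 7 of 7 each, inflammasome genes in 11 of 13, undifferentiated leukemia markers in 5 of 5, lysosome genes in 15 of 19 and p53 targets in 12 of 15 (camera adjusted p between 0.0071 and 0.04; adjusted p between 0.28 and 0.49 with an estimated correlation). Macrophage identity markers fell in 10 of 13 and rose in 2 (camera adjusted p = 0.043; adjusted p = 0.32 with an estimated correlation), a call that ended without control replicate 1 (adjusted p = 0.061) or 2 (adjusted p = 0.056). Of the list of non-myeloid markers, PECAM1 and VWF stood at 105 ± 0.79 and 6.85 ± 0.27. In total 7359 genes (96.2%) changed by limma, 3720 upward and 3639 downward, and camera called 14 lists, 4 higher and 10 lower, and 0 with an estimated correlation.

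The effect of glucose during foam cell formation, the question in the title of the series, was addressed by oxLDL plus glucose against oxLDL. The differences had a median size of 0.102 log2 units among the genes listed, which held few that were alike in control and oxLDL cells, so genes that glucose alone changes were hardly covered. None of the genes named next, which had the smallest p among those with a symbol and a mean of at least 3 log2 units, passed the test. MMP3, a matrix protease, stood at 370 ± 20 with glucose and 226 ± 16 without (SD, n = 2; log2 fold change 0.71, SE 0.07, limma with Benjamini-Hochberg adjusted p = 0.051), and 211 ± 4.3 in control. SLC5A3, which imports the osmolyte myo-inositol, stood at 37.9 ± 1.9 against 23.6 ± 0.59 (limma adjusted p = 0.051) and CCL2 at 13 ± 0.21 against 8.27 ± 0.35 (limma adjusted p = 0.052). RGS16, a brake on G protein signaling, stood at 279 ± 14 against 191 ± 6.6 (limma adjusted p = 0.052).

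Log2 differences of the neutrophil chemokine CXCL2, the transcription factor JUN and the prostaglandin synthase PTGS2 were 0.60, 0.50 and 0.64 (limma adjusted p between 0.066 and 0.071). Those of MRPS6, a mitochondrial ribosomal protein, PRG2 and the cytokine TNFSF15 were 0.50, 0.62 and 0.39 (limma adjusted p between 0.073 and 0.085). DENND3, an activator of the GTPase RAB12, was lower with glucose, at 13.2 ± 0.64 against 21.1 ± 1.7 (limma adjusted p = 0.071). SLC5A3 (ENSG00000198743, chromosome 21 at 34073570 to 34106262) and MRPS6 (ENSG00000243927, 34073224 to 34143034) share exons on the same strand, so their values are not independent. MMP3 (ENSG00000149968) lies on chromosome 11 at 102835801 to 102843803 and CCL2 (ENSG00000108691) on chromosome 17 at 34255218 to 34257203.

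**Figure D3:**
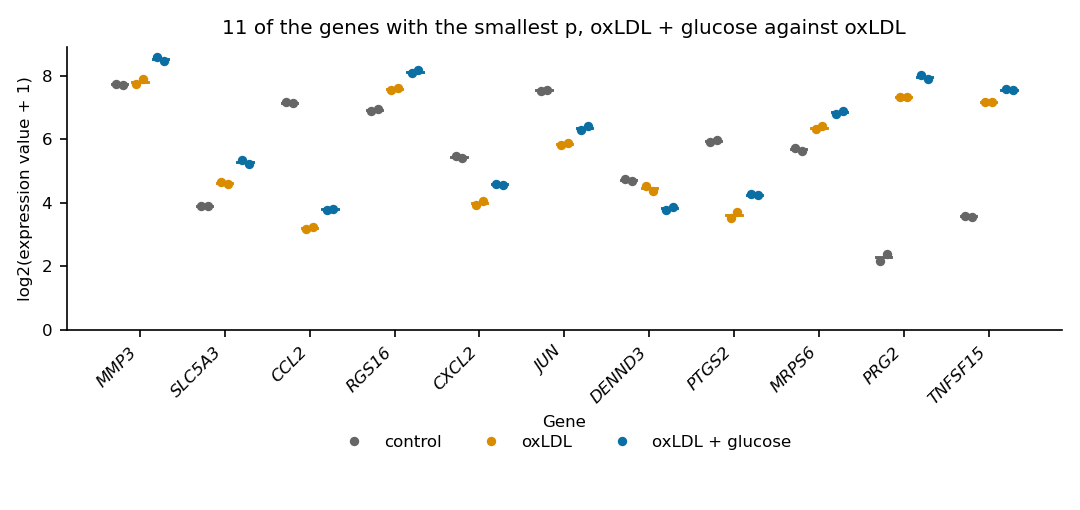
Expression of 11 genes chosen for the smallest p between oxLDL plus glucose and oxLDL among genes with a symbol and a mean of at least 3 log2 units, as log2(value + 1) on the vertical axis, with dots for the 2 libraries of each group and a line at the mean. MMP3 stands at 370 with glucose and 226 without, and none of the 11 genes passes at an adjusted p of 0.05.

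Of the genes chosen in advance, ABCA1 and CD36 differed between the oxLDL groups by log2 fold changes of 0.05 and −0.07 (SE 0.07 and 0.12; limma adjusted p = 0.84 and 0.88). Differences of OLR1, PLIN2, TXNIP and HMOX1 were −0.26, −0.27, 0.22 and 0.19 (limma adjusted p between 0.26 and 0.44), those of ABCG1 and SLC2A1 −0.19 and −0.13 (limma adjusted p = 0.67 and 0.70), and that of MSR1 −0.86 (limma adjusted p = 0.54). MSR1 stood at 0.208 and 2.67 in the oxLDL libraries against 0.0934 and 0.224 with glucose, and its difference was 0.07 once a share of the control level was subtracted from oxLDL replicate 2. The share subtracted exceeded the value of MSR1 in that library, so the change of sign came from the subtraction.

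A single gene passed, AL162417.1 (ENSG00000285245, protein coding, chromosome 9 at 133098121 to 133163914), at 3.03 and 2.1 with glucose and listed at 0 in the oxLDL and control libraries (limma adjusted p = 0.023). It shares exons on the same strand with RALGDS, which stood at 1.28 and 1.62 against 3.68 and 4.12, and with GBGT1, at 3.9 and 3.83 against 6.34 and 6.94, and is therefore uncertain. Likewise BORCS7-ASMT, at 2.49 and 2.3 with glucose and listed at 0 in both oxLDL libraries, shares exons on chromosome 10 with AS3MT, at 0.106 and 0.156 against 2.13 and 1.85. Of 24 genes at an adjusted p under 0.1, 17 higher and 7 lower, 19 had an annotation and 8 of these shared exons with another listed gene on the same strand. These overlaps, and the overlapping genes named, were examined after the values were seen. Of 7648 genes tested, 829 had an unadjusted limma p under 0.05, 420 higher and 409 lower. Unchanged genes also pass that threshold, at a rate of 0.05. The libraries of the groups did not overlap for 3141 genes (41.1%), where chance gives 33.3%. The count of 1 moved to 10 without control replicate 1 or 2, 40 without oxLDL replicate 1, 5 without oxLDL replicate 2 and 0 without oxLDL plus glucose replicate 2. It was 0 with a replicate term, without a trend, with only the 4 libraries compared and with values of at least 5, and it was 5 (4 higher and 1 lower) after quantile normalization.

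Gene lists showed small shifts, and none of their members passed over all genes tested. The list of scavenger receptors lay lower with glucose, with 12 of 13 members below 0 and a median log2 fold change of −0.19 (camera adjusted p = 0.00028; adjusted p = 0.46 with an estimated correlation). Adjusted over the list alone 3 passed, all lower, OLR1, the particle receptor MARCO (log2 fold change −0.68) and the lipoprotein receptor LRP1 (−0.28), and this was the only list called with each library left out in turn, at an adjusted p of at most 0.0038, although a group reduced to 1 library takes its spread from the other groups. The NF-kB list lay higher, with a median of 0.16 (camera adjusted p = 0.0027; adjusted p = 0.47 with an estimated correlation). Adjusted over the list alone, 7 of its genes were higher (CXCL1, CXCL2, CXCL3, CCL2, CCL7, PTGS2 and TNF) and 2 lower (TNFAIP3 and EBI3), and the list was not called without oxLDL replicate 1 (adjusted p = 0.065). The list of glucose-responsive genes and glucose side pathways lay higher, with 7 of 10 members above 0 and 3 below. Its median was 0.16 (camera adjusted p = 0.006, and camera adjusted p = 0.46 with an estimated correlation). Adjusted over the list alone 5 were higher, namely aldose reductase AKR1B1, the hexosamine enzyme GFPT2, TXNIP, ARRDC3 and the O-GlcNAc transferase OGT, and the call ended without oxLDL replicate 2 (adjusted p = 0.082).

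Interferon lists lay lower in the presence of glucose, and this rested on oxLDL replicate 2. The interferon gamma list had a median of −0.19 (camera adjusted p = 0.00022; adjusted p = 0.57 with an estimated correlation) and the type I list one of −0.20 (camera adjusted p = 0.00028; adjusted p = 0.57 with an estimated correlation), with 1 gene of each lower when adjusted over the list alone. Without oxLDL replicate 2, which held the 41 control-type transcripts at a median of 1.45% of the control level, the medians were −0.04 and −0.02 (camera adjusted p = 0.36 and 0.47). Log2 fold changes with all libraries were −0.63 for HLA-DMA, −0.30 for CD74, both of class II antigen presentation, and −2.58 for IDO1, −1.05 for IFITM1 and −0.71 for IFITM3 (limma adjusted p between 0.19 and 0.39). IDO1 stood at 1.71 and 25.4 in the oxLDL libraries, and the difference of IFITM3 was 0.60 once the control share was subtracted from oxLDL replicate 2. The share subtracted exceeded the value of IFITM3 in that library, so this change of sign does not show a rise with glucose. Before it, IFITM3 stood at 2.35 and 5.1 with oxLDL against 1.61 and 1.93 with glucose. IFI27 was listed at 0 in both glucose libraries and at 0.518 and 0.943 in the oxLDL libraries. HLA-DMA and IFI27 were the genes that passed over their list alone. HLA-DMA stood at 1.63 and 1.58 with oxLDL against 0.568 and 0.82 with glucose. These values are low, and both genes stood lower with glucose than in either oxLDL library. IFITM1 and IFITM3 are close paralogs and their values are uncertain.

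Further lists were lower by camera with small medians. Cell cycle genes had a median of −0.10 (camera adjusted p = 0.011; adjusted p = 0.46 with an estimated correlation) and lysosome genes one of −0.06 (camera adjusted p = 0.012; adjusted p = 0.47 with an estimated correlation). Log2 fold changes were −0.46 for TK1, −0.35 for the helicase subunit MCM2, −0.35 for cyclin A2 (CCNA2) and −0.36 for the lysosomal cholesterol carrier NPC2 (limma adjusted p between 0.26 and 0.33), while CTSL stood at 0 and 0.181 against 3.4 and 54 (limma adjusted p = 0.29). Alternative activation genes had a median of −0.12 (camera adjusted p = 0.018; adjusted p = 0.47 with an estimated correlation), macrophage identity markers one of −0.07 (camera adjusted p = 0.021; adjusted p = 0.46 with an estimated correlation) and NADPH oxidase genes one of −0.17 (camera adjusted p = 0.021; adjusted p = 0.46 with an estimated correlation). Adjusted over the list alone, none passed among cell cycle, lysosome and macrophage identity genes, 2 alternative activation genes were lower, and 1 NADPH oxidase gene was higher and 3 lower.

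These calls moved with single libraries. Without oxLDL replicate 2 those of cell cycle, alternative activation, macrophage identity and NADPH oxidase genes ended (adjusted p between 0.079 and 0.099), and without oxLDL replicate 1 those of cell cycle, macrophage identity and NADPH oxidase genes did (adjusted p = 0.11, 0.23 and 0.059). Without oxLDL plus glucose replicate 1 the lysosome, alternative activation and macrophage identity lists were not called (adjusted p = 0.10, 0.19 and 0.055), and macrophage identity was also lost without either control library (adjusted p = 0.094). Ribosomal protein genes, with a median of 0 and not called with all libraries, were called lower without oxLDL plus glucose replicate 1 (adjusted p = 0.0028) and higher without replicate 2 (adjusted p = 0.021). In total camera called 10 lists, 2 higher and 8 lower, 3 of them without oxLDL replicate 2 and 0 with an estimated correlation.

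The 2 relations between comparisons that were computed run across genes, which are not independent replicates. Log2 fold changes of oxLDL and of oxLDL plus glucose against control correlated with r = 0.989 (Spearman rho 0.978), where simulated unchanged groups sharing the controls gave r = 0.498. The covariance was 2.14 against 0.00982 in the simulation, a difference of 2.13, and r was 0.977 and 0.979 when each control library entered a single contrast. In both, 3636 genes were higher and 3548 lower, where independent lists would share 1792 and 1742, and 1 gene without a name, newGene_6357, had opposite calls. Both comparisons use the same controls and called 96.1% and 96.2% of the genes tested. The calls could not be independent, so the excess is no measure of agreement. The simulated genes were not chosen for a difference from control, whereas the listed genes held almost none alike in control and treated cells. The simulated r of 0.498 and covariance of 0.00982 are therefore not chance values for these genes. The difference of 2.13 is no measure of agreement either, and the r of 0.989 describes the listed genes only. Log2 fold changes of oxLDL against control and of oxLDL plus glucose against oxLDL gave r = 0.123 (rho 0.0199) against −0.502 in the simulation, with a covariance of 0.0392 against −0.00993. The simulated groups lacked the oxLDL change as well, which had a median size of 0.978 log2 units in the data. The r of −0.502 is therefore not the value to be had without a glucose effect, and the r values cannot be set against each other. The observed r was 0.279 and −0.00744 when each oxLDL library entered a single contrast.

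**Figure D4:**
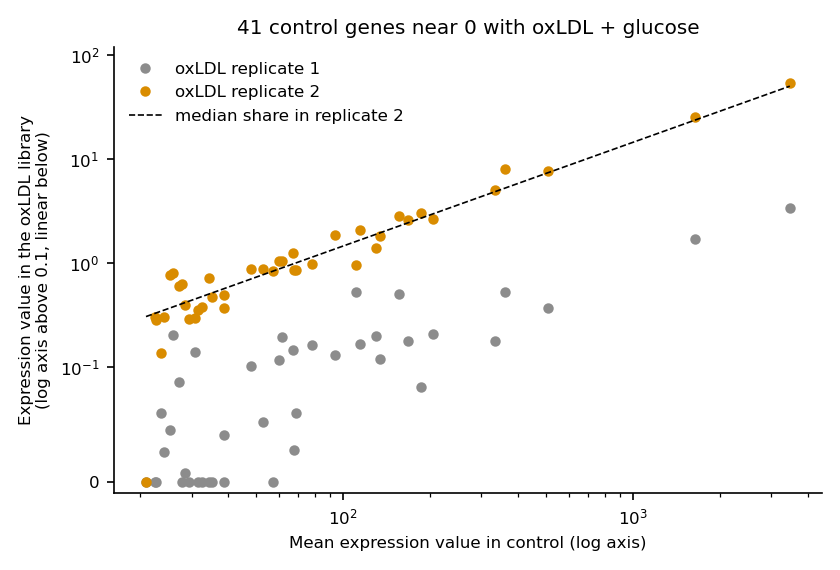
The 41 transcripts abundant in control and close to 0 with oxLDL plus glucose, with the control mean on the horizontal axis and the value in each oxLDL library on the vertical axis. The points of oxLDL replicate 2 lie at a median of 1.45% of the control mean, above those of replicate 1 at 0.102%.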

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

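The stricter filter, the fit without a trend and the subtraction of a control share were chosen only after the result was seen. Planned count-based tests, count scaling and the minimum of 50 counts were not run, since the values are not counts. Gene counts against control stayed within a factor of 1.5 in all settings except a minimum log2 fold change of 1, which left 3699 genes for oxLDL and 3723 for oxLDL plus glucose, and with each library left out they ran from 6250 to 7301 and from 6265 to 7319. Quantile normalization moved the median log2 fold change of oxLDL against control from −0.042 to 0.081. For oxLDL plus glucose against oxLDL the count of 1 was 5 after quantile normalization, 14 with the control share subtracted, and 0 with values of at least 5, with the replicate block, without a trend and with only the 4 libraries compared, and it ran from 0 without oxLDL plus glucose replicate 2 to 40 without oxLDL replicate 1. The cause was not tested.

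Lists called were 0 in each comparison with an estimated correlation, a run that rests on 3 residual degrees of freedom, and 27, 26 and 4 with fry. With each library left out, where a group of 1 library takes its spread from the other groups, they ran from 12 to 14 against control, where undifferentiated leukemia markers had under 5 tested members without either control library, and from 3 without oxLDL replicate 2 to 12 without oxLDL plus glucose replicate 2 between the oxLDL groups. The replicate block gave 7354, 7372 and 0 genes. The results reported used no replicate block, as planned, because the labels do not say that equal replicate numbers share a culture or day. Deviations of equally numbered libraries correlated at −0.019, 0.013 and −0.036.

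The correlation of the changes against control was 0.992 with values of at least 5, 0.985 with a pseudocount of 0.1, 0.978 with each shared library in one contrast, and 0.984 to 0.988 with libraries left out. The correlation of the oxLDL change with the glucose difference changed sign, at −0.032 with the control share subtracted and −0.0701 without oxLDL replicate 2, and reached 0.191 without oxLDL replicate 1. Glucose differences of single genes changed sign for IFITM3 (0.6) and MSR1 (0.07) with the control share subtracted, where that share exceeded their values in oxLDL replicate 2. CD36 ran from −0.24 without oxLDL plus glucose replicate 1 to 0.1 without replicate 2.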

Other observations

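The genes in the next paragraphs are list members chosen after their values were seen. Lipid genes that rose with oxLDL included the lipoprotein APOE, from 102 ± 2.6 to 1120 ± 21 (SD, n = 2), and APOC1, from 17.8 ± 1.2 to 117 ± 8.8. The lysosomal lipase LIPA had a log2 fold change of 1.68, the triglyceride synthase DGAT2 rose from 24.3 ± 0.24 to 242 ± 1.3 and the fatty acid oxidation enzyme ACADVL from 29 ± 0.03 to 233 ± 2.2. TREM2, a lipid-sensing receptor, rose from 12 ± 1 to 65.2 ± 4.1. Lipoprotein lipase LPL fell from 51.3 ± 1 to 2.44 ± 0.5, and the fatty acid ligase ACSL1 and SOAT1, which makes cholesteryl esters, had log2 fold changes of −2.05 and −1.57.

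Genes of the matrix list, of which 8 rose and 8 fell, included proteases that rose, MMP1 from 451 ± 0.23 to 3580 ± 150, MMP9 from 529 ± 5.3 to 3120 ± 15 and MMP10 from 34.5 ± 2.9 to 320 ± 14, together with their inhibitor TIMP1, from 2550 ± 49 to 5930 ± 90, while the neutrophil collagenase MMP8, the elastase MMP12 and the plasminogen activator PLAU fell (log2 fold changes −5.76, −1.18 and −2.07). Of the hexokinases, HK3 rose from 1.36 ± 0.17 to 20.7 ± 0.79 and HK1 fell (log2 fold change −2.13), while HK2, the most abundant of these, fell from 150 ± 8.1 to 98 ± 1.4. The growth factor receptor CSF1R fell from 193 ± 2.9 to 88.2 ± 3.5, while the antibacterial enzyme LYZ rose from 56.8 ± 0.31 to 478 ± 11. The DNA sensor AIM2 had a log2 fold change of −5.94. With glucose, APOE stood at 1070 ± 26, MMP1 at 4300 ± 550, HK3 at 23.5 ± 0.15 and LYZ at 464 ± 19.

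Of the tests that follow, the loss of the interferon shift without oxLDL replicate 2 and the osmotic genes not yet seen were set down before their result, and the others, with the leaving out of libraries for the osmotic genes, were chosen only after the result was seen. CXCL10, IDO1 and CTSL belonged to the 41 control-type transcripts in oxLDL replicate 2, which could come from about 1.45% of control RNA or of control-like cells in that library. Interferon or NF-kB genes (12) and other genes (29) had medians 0.191 percentage points apart (permutation p = 0.393), which does not show their shares to be equal. The interferon gamma shift with glucose was −0.04 without that library. A residual interferon response is not excluded by the median of 1.34% among the other genes. Genes outside the short lists may answer to interferon too, and HLA-DRB5, at 1.82%, was counted there. Reads exchanged alike among pooled libraries would reach both oxLDL libraries, where replicate 1 had 0.0703 of the share of replicate 2.

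The near absence of CTSL, MSR1 and IDO1 in treated cells may have several origins. Failed estimates in the authors' quantification would give zeros in oxLDL replicate 2 as well, where 97.6% of the 41 genes were above 0. In oxLDL replicate 1, 30 of them were above 0. These values speak for the oxLDL libraries only, and those of replicate 2 could come from control RNA. The genes were selected for low values in the oxLDL plus glucose libraries, so failed estimates there are left open. Loss of the interferon gamma and LPS signal could account for a part, since 29.3% of these genes belong to the interferon or NF-kB lists. UBB, a housekeeping ubiquitin gene, was among the 41, at 0.107% and 1.54% of the control level in the oxLDL libraries and listed at 0 in both oxLDL plus glucose libraries. The labels do not say whether control and treated libraries came from the same starting culture.

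SLC5A3, the betaine transporter SLC6A12 and AKR1B1, which makes sorbitol, had log2 differences of 0.66, 0.54 and 0.35 with glucose, none passing (limma adjusted p = 0.051, 0.12 and 0.17). Of 5 further osmotic genes listed before their values were seen, SLC6A6, SGK1, AQP1 and HSPA1B were above 0 and LTB was at −0.10, with a median of 0.24, at percentile 99.6 of 10000 random lists of the same size. That median fell to 0.04 without oxLDL plus glucose replicate 2, under the bound of 0.1 set for the test, and lay between 0.12 and 0.24 without each other library. Whether these genes answered to osmotic load is therefore left open. No osmotic control was among the libraries, so an effect of glucose itself could give the same values.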
